A study of Mus musculus with 6 samples.

How the data were processed

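Groups were taken from the sample titles, which name Pam3CSK4 with or without DA and a replicate number, and DA was read as dopamine from the title of the series. The source field spelled the ligand with a different final digit in each DA library, and the titles were followed. According to the labels, bone marrow cells of 8-week-old C57BL/6 mice were cultured for 4 to 6 days in medium with 10% fetal bovine serum and 10% L929 conditioned medium. The libraries were sequenced on a BGISEQ-500.

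The deposited files held, for each library and gene, expected counts, which per the file headers are the authors' estimates of the reads that belong to a gene and were not normalized. The same files held FPKM values, which the authors had scaled by transcript length and by the number of fragments in the library. The submitters' processing notes name Bowtie2 2.2.5 and the genome build GRCm38.p5, and the quantifier was not given in the sources used here. The genes carry Entrez identifiers and RefSeq transcripts. Each file lists only genes with an FPKM of at least 0.01, so a gene absent from a file was set to 0, and no upper limit was given for an absent gene. Of 17951 genes listed in at least 1 library, 13940 were listed in all 6. Genes of the mitochondrial genome were not found among the symbols, so the mitochondrial share was not analysed here.

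The expected counts were rounded to whole numbers, edgeR's filterByExpr removed 5561 genes, and the remaining 12390 were normalized with TMM factors (mean 0.969 with Pam3CSK4 and 1.032 with DA). edgeR's quasi-likelihood test compared 3 Pam3CSK4 plus DA libraries with 3 Pam3CSK4 libraries, with no replicate block, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A log2 fold change is the DA group minus the Pam3CSK4 group. Its standard error was taken as its size divided by the square root of the quasi-likelihood F statistic. Values in CPM are counts divided by the TMM-scaled library size and multiplied by 1e+06, given as mean ± SD over the 3 libraries of a group. The 12390 genes tested form 1 family of tests. The common dispersion gave a biological coefficient of variation of 0.056.

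The gene lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined. The 25 pathway lists covered pro-inflammatory cytokines, chemokines, NF-kB feedback, Toll-like receptor signalling, inflammasomes, interferon-stimulated genes, cAMP and CREB targets, NRF2 targets, iron and metal handling, the integrated stress and unfolded protein response, heat shock, p53 targets, alternative activation, hypoxia, glycolysis, oxidative phosphorylation, cholesterol synthesis, LXR targets and lipid efflux, cell cycle, antigen presentation and costimulation, prostanoids and leukotrienes, nitric oxide and arginine metabolism, lysosomes, macrophage identity, and catecholamine receptors and metabolism. The 10 cell type lists held markers of neutrophils, B cells, T and NK cells, dendritic cells, mast cells and basophils, eosinophils, erythroid cells, megakaryocytes, stromal cells and fibroblasts, and endothelial cells. Lists with at least 3 tested members were tested with camera, two-sided, at a preset correlation of 0.01, with adjustment over the lists of a kind. camera asks whether the genes of a list moved up or down on balance relative to other genes. camera can therefore leave a list uncalled although many of its members changed, when some rose and others fell. It was repeated with a correlation estimated per list, and fry, which asks only whether the genes of a list move one way on balance, was run beside it. Gene Ontology terms from the files with 10 to 300 tested genes were tested the same way.

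Named genes were those with an adjusted p under 0.05, a mean of at least 5 CPM and groups that do not overlap: the 12 with the largest rise and the 12 with the largest fall, leaving out predicted and unnamed genes. Up to 2 members that rose and 2 that fell, with the smallest adjusted p, were added from each pathway list. Tnf, Il1b, Il6, Il12b, Il10, Nlrp3, Tlr2, Nos2, Ptgs2, Hmox1 and the receptors Drd1 to Drd5 were named whatever their result. Genes outside this rule are said to be chosen after their values were seen, and the ferritin gene Fth1 is one of them.

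The alternatives were DESeq2's size factors and upper-quartile factors in the edgeR fit, DESeq2's Wald test, limma with a trend on log2(FPKM + 1) or log2(FPKM + 0.1) for genes with an FPKM of at least 1 in at least 3 libraries, limma without that filter, counts without a filter or with a mean of at least 50, the replicate number as a block, and each library left out in turn. Leaving the 50 most abundant genes out of the library sizes and the normalization was added after seeing the data. Shares of counts were compared by a two-sided exact permutation test over 20 assignments. These values have no interval beyond their SD, and any floor or interval from counts would cover counting error only. Gene positions, genomic spans and GC content came from GENCODE's gene models for GRCm38, joined by Entrez identifier.

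The steps were tested on simulated data with 12258 tested genes and the spread of these libraries. edgeR recovered 55.1% of genes changed 1.25-fold, 79.6% of those changed 1.5-fold, 89.6% of those changed 2-fold and 100% of those changed 4-fold, and called 0.12% of unchanged genes. camera called 0 of the 25 lists on unchanged data and 1 when only the lysosome list was shifted. The simulated genes varied independently of each other, whereas the correlation estimated for the interferon-stimulated list was 0.708. This run therefore cannot show how often camera calls lists of correlated genes falsely. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.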

Results

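The data were gene expression profiles of mouse bone marrow-derived macrophages (BMDMs), primary cells grown from the marrow of 8-week-old C57BL/6 mice in medium with L929 conditioned medium, a source of macrophage growth factor. All 6 libraries came from cells stimulated for 6 h with Pam3CSK4, a synthetic lipopeptide that activates Toll-like receptor 2 with Toll-like receptor 1. In 3 of them the cells had first been treated for 2 h with dopamine (DA), a catecholamine neurotransmitter, and the other 3 received Pam3CSK4 alone. Each library held between 21337932 and 21518425 expected counts, so depth was nearly equal, and 17951 genes were listed in at least 1 library. The single comparison the design gives is Pam3CSK4 plus DA against Pam3CSK4, which asks how DA alters the transcriptome of stimulated macrophages. No unstimulated cells and no cells given DA alone were analysed here, so a value in the Pam3CSK4 group is a stimulated level and not a baseline. The labels do not say that replicates came from separate mice or separate cultures, so the p-values measure the spread between these 6 libraries.

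The cytokine transcripts Il12b, Tnf and Il6 fell steeply in the DA group while Hmox1, Slc40a1 and Insig1 rose. Il12b, which encodes the shared subunit of interleukin-12 and interleukin-23, went from 173.1 ± 6.82 CPM (counts scaled to a common library size) with Pam3CSK4 to 2.87 ± 0.997 CPM with DA (mean ± SD, n = 3), a log2 fold change of -5.91 (SE 0.124). Tnf went from 3420 ± 288 to 392.5 ± 23.1 CPM (SD, n = 3), and Il6 from 249 ± 17.4 to 25.8 ± 0.924 CPM (SD, n = 3). In the opposite direction Hmox1, whose product heme oxygenase degrades heme, rose from 1339 ± 59.4 to 20710 ± 531 CPM (SD, n = 3), which is 15.5-fold. Slc40a1, encoding the iron exporter ferroportin, rose 19.2-fold, and Insig1, a feedback regulator of sterol synthesis, rose 7.78-fold. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 2.37e-13 for Il12b and 5.45e-15 for Hmox1, and for Il12b, Tnf, Il6 and Hmox1, which were named whatever their result, the 3 libraries of one group lay wholly above the 3 of the other.

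**Figure D1:**
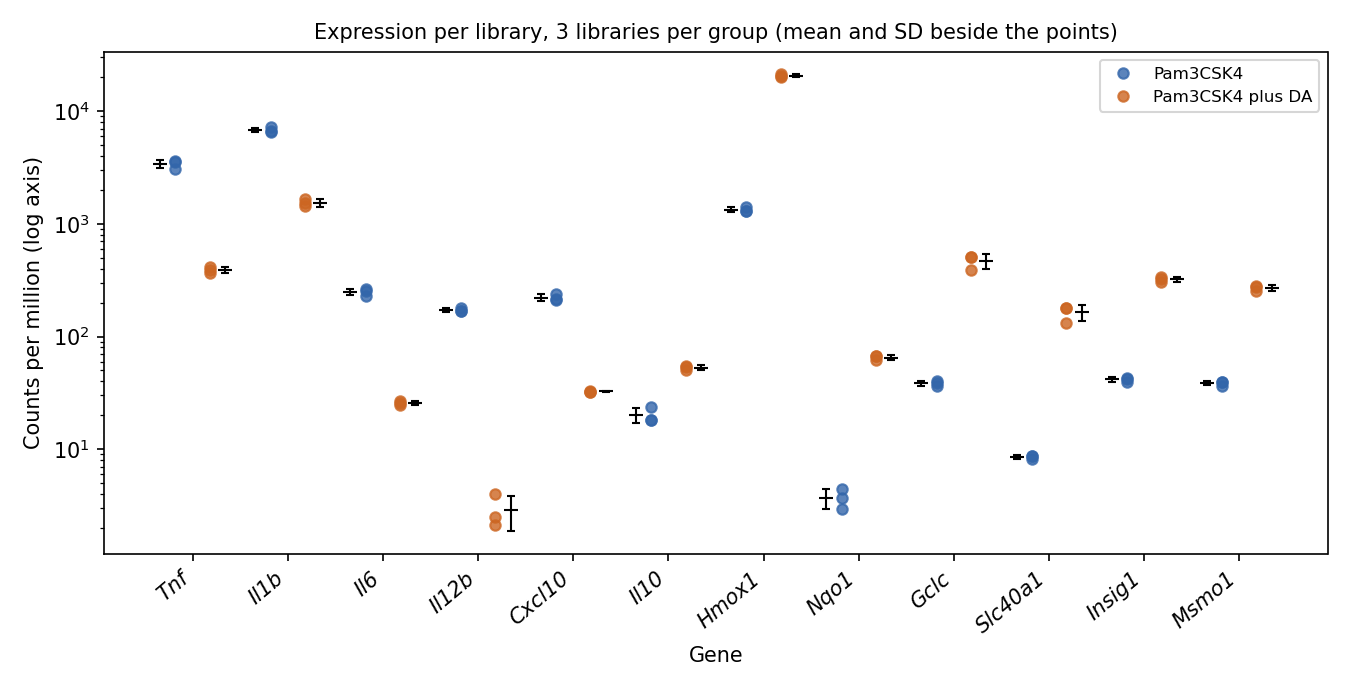
Expression of 12 named genes in each library, in CPM on a log axis; blue points are the 3 Pam3CSK4 libraries, orange points the 3 Pam3CSK4 plus DA libraries, and the black marks beside them give the mean and SD. Hmox1 moved from a mean of 1339 to 20710 while Tnf moved from 3420 to 392.5.

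Of 12390 genes tested, 4043 were higher and 3938 were lower with DA, so 64.4% changed at an adjusted p under 0.05 by edgeR's quasi-likelihood test. A change of at least 2-fold was called for 1837 genes, 910 of them higher and 927 lower. The groups did not overlap for 8513 genes (68.7%), where chance gives 10%. The balance between higher and lower calls depended on scaling: with upper-quartile factors, which moved the median log2 fold change of all tested genes from 0.02 to 0.135, the split was 5055 higher and 3138 lower, and on the deposited FPKM values with limma it was 4229 and 2858. The limma test on log2(FPKM + 1), a scale that understates the change of low genes, called 939 genes at least 2-fold changed.

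**Figure D2:**
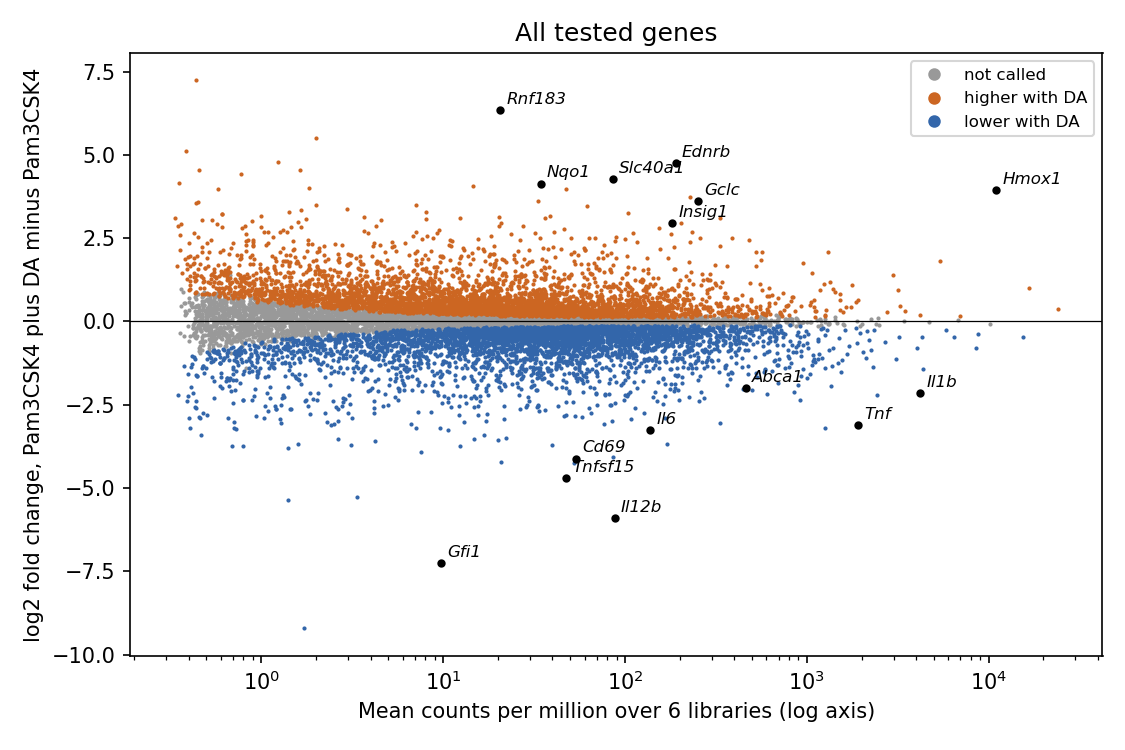
All 12390 tested genes by mean CPM over the 6 libraries (log axis) and log2 fold change of Pam3CSK4 plus DA minus Pam3CSK4; orange points were called higher, blue points lower and grey points were not called, with 15 genes labelled in black. Hmox1 stands out as both abundant and strongly higher, and Il12b and Gfi1 lie far below 0.

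The largest rises among genes with a mean of at least 5 CPM came from Rnf183 (log2 fold change 6.33, SE 0.153), which encodes a RING-finger ubiquitin ligase, and Ednrb (27.0-fold), the endothelin B receptor. Rnf183 went from 8 to 13 counts per library with Pam3CSK4 to between 820 and 994 with DA. Slc40a1, Nqo1 and Hmox1 were among the 12 largest rises, together with Ptgr1, which encodes an enzyme that reduces prostaglandins and leukotrienes, Gclc, which encodes the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, and Arg1, the cytosolic arginase. Their log2 fold changes were 3.74 (SE 0.063) for Ptgr1, 3.60 (SE 0.1) for Gclc and 3.48 (SE 0.173) for Arg1. The group of 12 also held Rabgap1l, a Rab GTPase-activating protein gene (log2 fold change 3.97), Lrp8, a lipoprotein receptor gene (3.48), and Cdk5r1, which encodes an activator of the kinase Cdk5 (3.27). Each of the 12 had an adjusted p of 5.65e-10 or lower.

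The steepest fall among genes with a mean of at least 5 CPM was that of Gfi1, a transcriptional repressor of myeloid development, which had 352 to 465 counts per Pam3CSK4 library and only 1, 3 and 4 counts in the DA libraries, so its log2 fold change of -7.25 (SE 0.247) rests on 8 counts on the DA side. Beside Il12b, the list of largest falls held the cytokine genes Tnfsf15 (log2 fold change -4.71, SE 0.148) and Il27 (-4.22, SE 0.101), the early activation antigen gene Cd69 (-4.12, SE 0.079), and Ch25h (-3.72, SE 0.086), whose product makes 25-hydroxycholesterol. Shisa3 (-4.26), Hivep3 (-4.08), Peg10 (-3.91), Lad1 (-3.74), the ceramide synthase gene Cers6 (-3.69) and Trerf1 (-3.57) completed it. In GENCODE's annotation of GRCm38, Il12b lies on chromosome 11 from 44400063 to 44414033, Hmox1 on chromosome 8 from 75093621 to 75100589 and Gfi1 on chromosome 5 from 107716657 to 107726036, all protein-coding genes. Cers6, Hivep3 and Trerf1 span 252.8, 404.3 and 221.1 kb. Across 11937 tested genes with a gene model, which are not independent replicates, the log2 fold change and the genomic span had a Spearman correlation of -0.384.

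Among the 21 genes of the pro-inflammatory cytokine list, all tested, 16 fell and 2 rose with DA, and 12 fell at least 2-fold. Il1b went from 6838 ± 315 to 1542 ± 118 CPM (SD, n = 3; log2 fold change -2.15). The median over the list was -1.82, and camera called it lower at an adjusted p of 3.77e-18 (adjusted p = 0.0102 with an estimated correlation). The list also holds genes of anti-inflammatory products, and 1 of the 2 that rose was one of these, Il10, which rose from 20.1 ± 3.07 to 52.9 ± 2.56 CPM (SD, n = 3; log2 fold change 1.40, SE 0.09). The other was Osm (log2 fold change 0.248), whose call was lost without Pam3CSK4 replicate 2 (0.215), without DA replicate 1 (0.198) and without DA replicate 3 (0.223). The counts adjusted over the list alone were also 16 and 2.

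Chemokine genes moved the same way: 15 of 20 tested fell and 3 rose, both over all genes and adjusted over the list alone, with a median log2 fold change of -1.37. Cxcl10, an attractant of T cells, fell 6.79-fold and Ccl4, an attractant of monocytes and T cells, fell 4.37-fold. Cxcl3 (log2 fold change 0.44) and Cxcl5 (1.36) were 2 of the 3 that rose. camera gave the chemokine list an adjusted p of 1.58e-12, with adjusted p = 0.112 with an estimated correlation.

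All 20 NF-kB feedback genes fell, also when adjusted over the list alone, 9 of them at least 2-fold (camera adjusted p = 2.43e-16; adjusted p = 0.0102 with an estimated correlation). Nfkb1, which encodes the p105 precursor of an NF-kB subunit, fell from 720.8 ± 35.9 to 175.8 ± 5.41 CPM (SD, n = 3), and the TNF-induced gene Tnfaip2 fell 2.89-fold. With upper-quartile factors 19 of the 20 fell.

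Toll-like receptor signalling genes were divided, with 10 of 20 lower and 6 higher, the same when adjusted over the list alone, and with 8 lower and 8 higher under upper-quartile factors. The list was not called by camera (adjusted p = 0.0601; adjusted p = 0.469 with an estimated correlation). The ligand's own receptors fell, Tlr2 from 922.8 ± 12.8 to 414.3 ± 21 CPM (SD, n = 3; log2 fold change -1.16, SE 0.052) and its partner Tlr1 by 2.80-fold, as did the signalling kinase gene Irak2 (log2 fold change -2.04). Tlr4, the receptor for lipopolysaccharide, rose 2.65-fold, and Ikbkg, the regulatory subunit of the IkB kinase, rose 1.95-fold.

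Inflammasome genes were split, with 8 of 16 lower and 7 higher over all genes and adjusted over the list alone (camera adjusted p = 0.398). Nlrp3, the sensor of the NLRP3 inflammasome, went from 1151 ± 65.1 to 481.9 ± 18.4 CPM (SD, n = 3; log2 fold change -1.26), whereas Casp1, the protease that cleaves pro-interleukin-1 beta, rose 1.57-fold and Naip2 rose 1.75-fold. Naip2 has near-identical relatives that may share reads, so its value is uncertain.

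**Figure D3:**
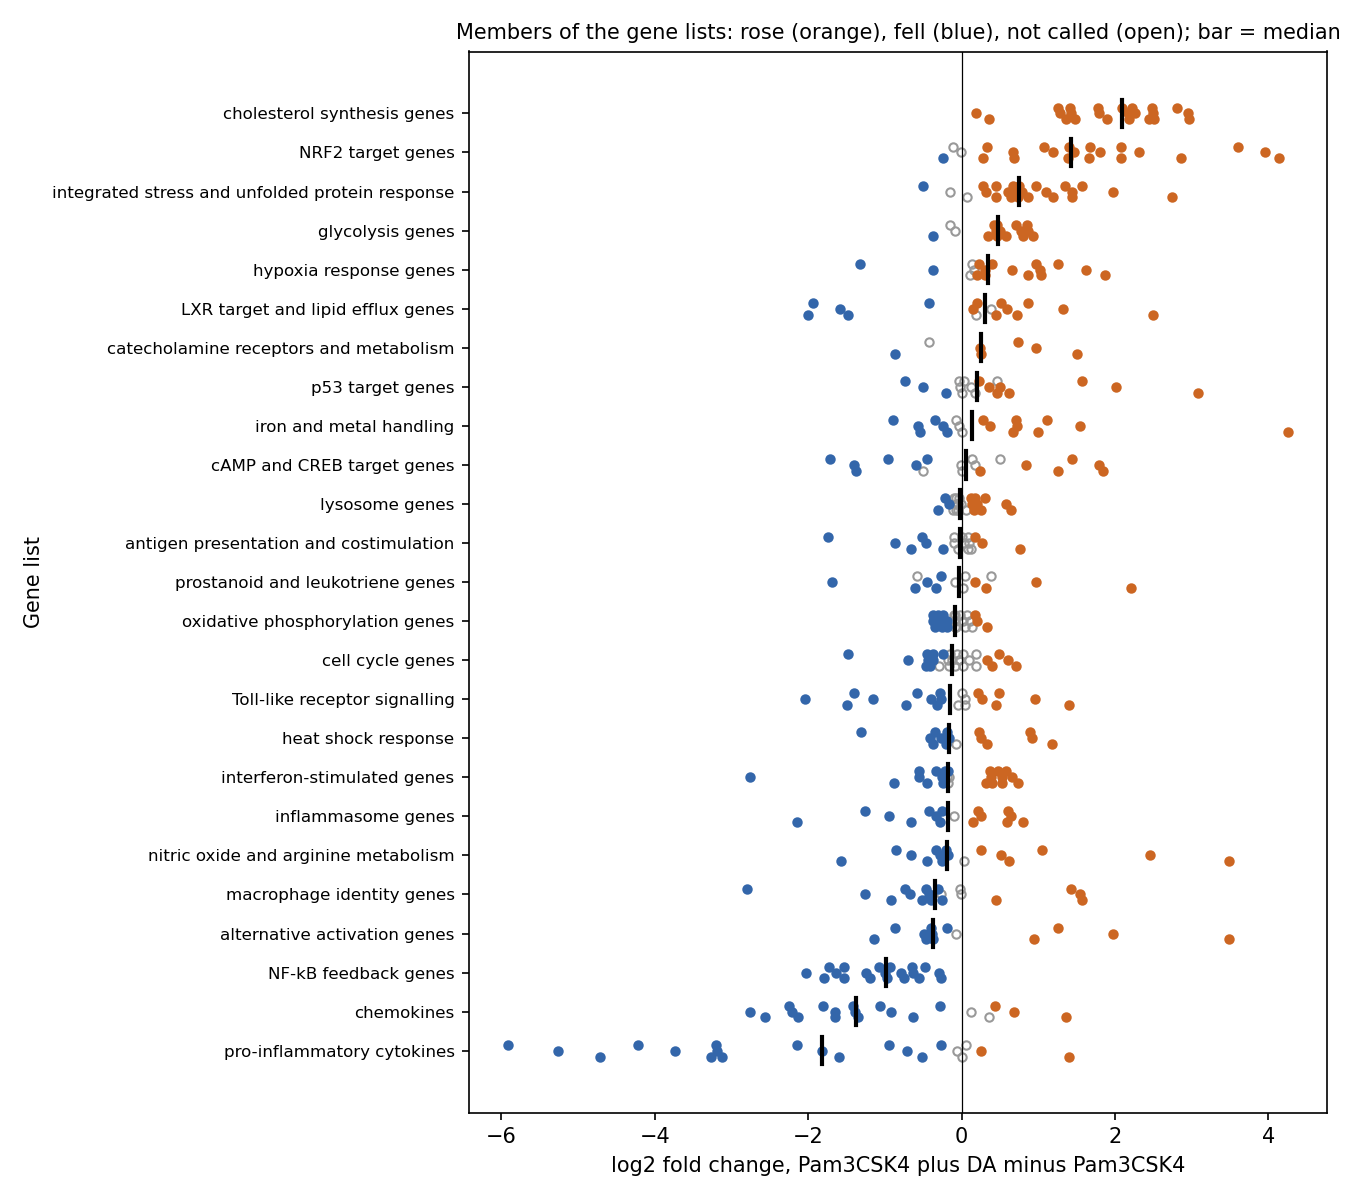
log2 fold change of each tested member of the 25 gene lists, Pam3CSK4 plus DA minus Pam3CSK4; orange points rose, blue points fell, open points were not called, and the bar is the list's median. The cholesterol synthesis list has the highest median (2.09) and the pro-inflammatory cytokine list the lowest (-1.82).

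Interferon-stimulated genes showed no common direction: 10 of 23 rose and 10 fell (11 fell adjusted over the list alone; camera adjusted p = 0.732), and with upper-quartile factors 10 rose and 6 fell. Irf7, a transcription factor of the interferon response, rose 1.66-fold and the antiviral gene Oas2 rose 1.44-fold, while Mx2, annotated by GENCODE as a polymorphic pseudogene, fell 1.85-fold. cAMP and CREB target genes were equally divided, with 6 of 18 higher and 6 lower (7 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.844), and 8 higher and 6 lower with upper-quartile factors. Thbs1, which encodes the matrix protein thrombospondin-1, rose 3.60-fold and Vegfa, an angiogenic growth factor gene, rose 2.40-fold, while the orphan nuclear receptor gene Nr4a1 fell 3.29-fold and the cAMP phosphodiesterase gene Pde4b fell 2.60-fold.

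NRF2 target genes rose as a group, with 19 of 22 higher and 1 lower over all genes and adjusted over the list alone, and 15 higher by at least 2-fold. Nqo1, a quinone reductase gene, rose from 3.69 ± 0.724 to 65.2 ± 3.3 CPM (SD, n = 3; log2 fold change 4.14, SE 0.103), and Gclc from 38.5 ± 1.88 to 467.6 ± 70.6 CPM (SD, n = 3). The median of the list was 1.43, and camera gave an adjusted p of 2.87e-29 (adjusted p = 0.112 with an estimated correlation). The member that fell was Slc7a11, the cystine transporter gene (log2 fold change -0.25), whose call was lost with upper-quartile factors (-0.13), without Pam3CSK4 replicate 1 (-0.13), without DA replicate 2 (-0.17) and on FPKM.

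Iron and metal handling genes rose in 9 of 18 cases and fell in 6, the same counts adjusted over the list alone (camera adjusted p = 0.04; adjusted p = 0.338 with an estimated correlation). Slc40a1 went from 8.52 ± 0.296 to 163.8 ± 27.5 CPM (SD, n = 3), and Slc30a1, a zinc exporter gene, rose 2.92-fold. Slc39a14, a zinc and iron importer gene, fell 1.85-fold, and Ncoa4, whose product targets ferritin for breakdown, fell 1.45-fold. The call of this list was lost without Pam3CSK4 replicate 2 (adjusted p = 0.0519). The share of all counts in Fth1, the ferritin heavy chain gene, was 2.04% ± 0.0664 with Pam3CSK4 and 2.81% ± 0.147 with DA (SD, n = 3), a gene with processed pseudogenes that may share its reads.

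Genes of the integrated stress and unfolded protein response rose in 21 of 24 cases, with 1 lower (2 lower adjusted over the list alone) and a median log2 fold change of 0.75. camera gave this list an adjusted p of 1.38e-08 (adjusted p = 0.338 with an estimated correlation). Trib3, a pseudokinase gene induced by amino acid and endoplasmic reticulum stress, rose 6.68-fold, and Pdia4, an endoplasmic reticulum disulfide isomerase gene, rose 2.71-fold. Ppp1r15a, which encodes a subunit of the phosphatase that ends the stress response, fell 1.42-fold. Heat shock genes went both ways, with 6 of 15 higher and 8 lower, the same counts adjusted over the list alone (camera adjusted p = 0.987), and 6 higher and 4 lower with upper-quartile factors. Their median was -0.17 while their mean was 0.03 and the test's direction was down. The cochaperone genes Bag3 and Hsph1 rose 1.88-fold and 2.26-fold, and Hspa4, a chaperone gene, fell 1.33-fold. Hspa1b (-1.31) has a near-identical neighbouring copy, so its value is uncertain.

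Among 18 p53 target genes, 8 rose and 3 fell, also when adjusted over the list alone, and camera called the list higher at an adjusted p of 0.047 (adjusted p = 0.228 with an estimated correlation). Gdf15, a stress-induced cytokine gene, rose 4.05-fold and the kinase gene Plk2 rose 2.96-fold, whereas the antiproliferative gene Btg2 fell 1.67-fold. The call was lost with DESeq2's size factors (adjusted p = 0.0514), without Pam3CSK4 replicate 2 (0.0519) or 3 (0.0523), and without DA replicate 2 (0.0504).

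All 23 genes of cholesterol synthesis rose, over all genes and adjusted over the list alone, 21 of them at least 2-fold, with a median log2 fold change of 2.09. Insig1 went from 41.6 ± 2.16 to 323.6 ± 17.1 CPM (SD, n = 3; log2 fold change 2.96, SE 0.064), and Msmo1, a sterol methyl oxidase gene, from 38.6 ± 1.72 to 270.4 ± 14.5 CPM (SD, n = 3). camera gave an adjusted p of 1.15e-42, with adjusted p = 0.112 with an estimated correlation. In the list of LXR targets and lipid efflux genes, 9 of 16 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.844). Scd2, a fatty acid desaturase gene, rose 5.63-fold and Fasn, the fatty acid synthase gene, rose 2.49-fold. Lpl, the lipoprotein lipase gene, fell from 2149 ± 126 to 562.4 ± 30.9 CPM (SD, n = 3), and Nr1h3, which encodes the receptor LXR alpha itself, fell from 69.0 ± 3.86 to 23.0 ± 0.0849 CPM (SD, n = 3).

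Glycolysis genes rose in 13 of 16 cases with 1 lower, also when adjusted over the list alone (camera adjusted p = 0.000239; adjusted p = 0.387 with an estimated correlation). The changes were modest, with none at or above 2-fold. Pkm, the pyruvate kinase gene, rose 1.91-fold and Pgk1, the phosphoglycerate kinase gene, rose 1.83-fold, while the hexokinase gene Hk2 fell 1.29-fold. Hk1, a hexokinase gene chosen after its value was seen, rose 1.71-fold. Hypoxia response genes rose in 13 of 18 cases and fell in 2 (15 and 2 adjusted over the list alone; camera adjusted p = 0.00118; adjusted p = 0.112 with an estimated correlation). Mxi1, a MYC antagonist gene, rose 3.67-fold and Bnip3, a mitophagy gene, rose 2.03-fold, but Adm, encoding adrenomedullin, fell 2.51-fold. Oxidative phosphorylation genes moved little, with 9 of 24 lower and 3 higher over all genes and adjusted over the list alone (camera adjusted p = 0.732), and with 5 lower and 7 higher under upper-quartile factors. Atp5a1 (log2 fold change -0.37) and Sdha (-0.38) fell and Ndufa4 rose (0.33).

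Genes of alternative activation split, with 8 of 13 tested lower and 4 higher, also when adjusted over the list alone (camera adjusted p = 0.732). Arg1 rose from 1.16 ± 0.177 to 13.0 ± 2.21 CPM (SD, n = 3) and Klf4, a macrophage transcription factor gene, rose 3.94-fold. Tgm2 (-0.47) and the scavenger receptor gene Msr1 (-0.40) fell. The list's median was -0.37, while its mean was 0.25 and the test's direction was up. In nitric oxide and arginine metabolism, 6 of 16 rose and 9 fell over all genes and adjusted over the list alone (camera adjusted p = 0.9), with 6 and 5 under upper-quartile factors, and the median (-0.19) and mean (0.22) differed in sign. Arg2, the mitochondrial arginase gene, rose 5.49-fold, and Slc7a2, an arginine transporter gene, fell 2.98-fold. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, fell 1.81-fold. Nos2, the inducible nitric oxide synthase gene, had 37.3 ± 6.35 CPM with Pam3CSK4 and 29.5 ± 2 CPM with DA (SD, n = 3; log2 fold change -0.34, SE 0.102, adjusted p = 0.0095), a call lost without Pam3CSK4 replicate 2 (-0.20), without DA replicate 3 (-0.28), with upper-quartile factors (-0.22) and on FPKM.

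Prostanoid and leukotriene genes rose in 4 of 14 cases and fell in 5, the same adjusted over the list alone (camera adjusted p = 0.732), with 5 and 4 under upper-quartile factors. The median was -0.03 and the mean 0.01. Ptgs2, which encodes cyclooxygenase-2, fell from 1538 ± 226 to 477.7 ± 49.9 CPM (SD, n = 3; log2 fold change -1.69), and Pla2g4a, the cytosolic phospholipase A2 gene, fell 1.52-fold. Ptger2, a prostaglandin E2 receptor gene, rose 4.62-fold and Alox5ap, the partner of 5-lipoxygenase, rose 1.97-fold.

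Antigen presentation and costimulation genes were lower in 6 of 18 cases and higher in 3, also when adjusted over the list alone (camera adjusted p = 0.698), and lower in 5 and higher in 6 under upper-quartile factors. The costimulatory receptor gene Cd40 fell 3.34-fold and Cd274, which encodes the ligand of PD-1, fell 1.43-fold, while Cd86, another costimulatory gene, rose 1.70-fold. Among 18 macrophage identity genes, 11 fell and 4 rose, also when adjusted over the list alone (camera adjusted p = 0.425). The fractalkine receptor gene Cx3cr1 fell 6.93-fold and Adgre1, which encodes the F4/80 antigen, fell 2.39-fold. The myeloid transcription factor gene Cebpa rose 2.90-fold.

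Cell cycle genes were not called as a list (5 of 27 higher, 9 lower; 5 and 8 adjusted over the list alone; camera adjusted p = 0.732), and with upper-quartile factors 6 rose and 6 fell. The proliferation marker Mki67 fell 2.80-fold and the topoisomerase gene Top2a fell 1.63-fold, whereas Pcna, the replication clamp gene, rose 1.64-fold. Lysosome genes changed slightly, with 9 of 22 higher and 3 lower (8 and 3 adjusted over the list alone; camera adjusted p = 0.732) and 10 higher and 1 lower with upper-quartile factors, and their median of -0.02 differed in sign from the mean of 0.06. Ctsl, a cathepsin gene, rose 1.57-fold, Gla, the alpha-galactosidase gene, rose 1.49-fold, and Atp6v0d1, a proton pump subunit gene, fell 1.24-fold.

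Transcripts of the catecholamine system were scarce. Drd1 was listed with 8 counts in total over the 6 libraries, too few to test, and Drd2, Drd3, Drd4 and Drd5 were not listed in any library. Of 7 tested genes for catecholamine receptors and metabolism, 5 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.578). The adrenergic receptor gene Adra1a rose from a low level of 1.14 ± 0.158 CPM with Pam3CSK4 to 3.25 ± 0.733 CPM with DA (SD, n = 3), and Slc18a2, the vesicular monoamine transporter gene, fell 1.82-fold.

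Markers of other cells that a marrow culture could hold gave no list called by camera. That test compares the groups and does not ask whether such cells were present. Summed stromal and fibroblast markers had 19969 to 20866 counts per library with Pam3CSK4 and 18333 to 19829 with DA. The sums were 4800 to 5804 and 13536 to 13894 for neutrophil markers, S100a8 included, and 4963 to 6032 and 7918 to 9391 for megakaryocyte markers. Every other list had at most 434. Which cells held these transcripts was not tested. Of 9 tested neutrophil markers 3 rose and 2 fell (3 and 1 adjusted over the list alone; adjusted p = 0.255), with a median of -0.14 and a mean of 0.41. S100a8, singled out after its value was seen, rose from 63.5 ± 12.6 to 406.3 ± 14.6 CPM (SD, n = 3) while its usual partner S100a9 was at 93.2 ± 9.17 and 99.8 ± 2.9 CPM (SD, n = 3; adjusted p = 0.228). Of 4 megakaryocyte markers 2 rose (adjusted p = 0.379), of 7 stromal and fibroblast markers 4 fell (adjusted p = 0.255), and of 3 endothelial markers 1 fell (adjusted p = 0.99), with the same counts adjusted over the list alone. Too few members of the remaining lists were expressed for a list test. Of 2 T and NK cell markers 1 fell, of 2 dendritic cell markers 1 rose and 1 fell, the single mast cell and basophil marker rose and the single eosinophil marker fell, while no B cell or erythroid marker passed the filter.

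The list tests above used camera's preset correlation of 0.01. With the correlation estimated from these 6 libraries, the cytokine and NF-kB feedback lists kept their calls and the other 8 called lists lost them, and under the preset value other splits of the same libraries called up to 11 lists. Those splits mix both groups and carry part of the DA difference, so that number is not a rate of false calls. The estimated correlations of the p53 (-0.053), hypoxia (-0.012) and NF-kB feedback (-0.017) lists lay below the preset 0.01. Their camera p-values still rose, for NF-kB feedback from 3.89e-17 to 0.000778. Calls lost under the estimated correlation, also those of Gene Ontology terms below, therefore need not reflect correlated genes.

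The makeup of the libraries also differed between the groups. The 10 most abundant genes took 10.5% ± 0.264 of counts with Pam3CSK4 and 13.4% ± 0.283 with DA (SD, n = 3), and Hmox1 alone took 0.13% ± 0.00622 and 2.14% ± 0.0361 (SD, n = 3). The total count (exact two-sided permutation test, p = 0.6) and the share of ribosomal protein genes (3.36% ± 0.262 and 3.71% ± 0.209; p = 0.2 by the same test) showed no separation. The number of genes with at least 1 count was 15591 ± 27.7 and 15866 ± 49.2 (SD, n = 3; exact p = 0.1). Replication-dependent histone genes took 0.00807% ± 0.00013 and 0.0147% ± 0.0011 of counts (SD, n = 3; exact p = 0.1). With 3 libraries against 3, 0.1 is the smallest p this exact test can give. Libraries of one group correlated at 0.994 to 0.995 (Pearson, log2 CPM over genes) and libraries of different groups at 0.95 to 0.958, and the first principal component, which separated the groups, held 85.4% of the variance.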

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

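Leaving the 50 most abundant genes out of the normalization was chosen after seeing the data, and the other alternatives were planned. Of the 112 named genes tested, 105 kept their direction and call under every alternative run, and 7, among them Slc7a11, Nos2, Osm, Cox7b, Sesn1 and Hif1a, lost the call under at least 1, with 0 reversed. Changed genes numbered 7970 with DESeq2's size factors, 8193 with upper-quartile factors, 7178 with DESeq2's Wald test, 7907 without a filter, 7089 at a mean count of at least 50, 7984 without the 50 most abundant genes, and 7338 to 7735 when each library was left out in turn. Genes changed at least 2-fold numbered 939 by limma on log2(FPKM + 1), 928 without its filter, 1347 on log2(FPKM + 0.1) and between 1322 and 2077 by the remaining alternatives; a pseudocount of 1 shrinks the fold change of low genes by construction. With the replicate block 8334 genes changed, 4223 higher and 4111 lower, against 7981 without it. In that fit the heat shock (camera adjusted p = 0.942) and endothelial (0.985) lists reversed direction. Same-numbered libraries deviated from their group means with correlations of 0.1, -0.02 and 0.03. These values do not settle whether equal numbers pair the libraries, which the labels do not say. With an estimated correlation the adjusted p was 0.112 for chemokines, NRF2 targets, hypoxia and cholesterol synthesis, 0.338 for iron handling and for the stress response, 0.228 for p53 targets and 0.387 for glycolysis, and 0 terms were called up and 0 down by camera. In that run 42 of 752 process terms, 9 of 198 function terms and 6 of 160 component terms had an unadjusted p under 0.05. These shares lie near the 0.05 that chance gives. fry gave an adjusted p of 0.000907 for Toll-like receptor signalling and for the catecholamine list, 0.000972 for inflammasomes, 0.0245 for alternative activation, 0.0132 for antigen presentation, 0.0147 for lysosomes, 0.00519 for macrophage identity, 0.00285 for neutrophil and for stromal markers and 0.00362 for megakaryocyte markers, and called 237 terms up and 615 down; it does not compare a list with other genes. DESeq2's size factors gave p53 targets 0.0514, and the endothelial list reversed (0.997) without the 50 most abundant genes. With each library left out in turn the adjusted p ranged from 0.601 to 0.842 for interferon-stimulated genes, 0.0049 to 0.0519 for iron handling, 0.903 to 0.973 for heat shock, 0.0331 to 0.0523 for p53 targets, 0.455 to 0.973 for LXR targets, 0.736 to 0.959 for nitric oxide and arginine and 0.824 to 0.988 for endothelial markers. All of these but iron handling and p53 targets, neither of which reversed, changed direction in at least 1 of those fits without being called. Of the counts of called list members, 748 stayed within 1.5 times the reported count and 52 did not. The difference in the share of counts was 2.84 percentage points for the 10 most abundant genes, 2.13 for the 50 and 0.638 for the 200 most abundant. Apart from the pseudocount, the cause of these differences was not tested. At this depth edgeR recovered 55.1% of the smallest simulated changes, so small changes may be incompletely covered. The simulation left 12062 of 12258 genes unchanged, whereas 64.4% of tested genes were called in these data. Its recovery is therefore not a measure of sensitivity in this comparison.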

Other observations

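The tests of nuclear RNA, of LXR targets, of neutrophil markers and of abundant genes as a cause of the sterol pattern were chosen only after the result was seen. Gene Ontology terms were called by camera at the preset correlation, and none of the calls held with an estimated correlation. Of 30 tested genes for positive regulation of leukocyte chemotaxis, 21 fell and 3 rose (camera adjusted p = 5.84e-09; adjusted p = 0.806 with an estimated correlation). Of 91 genes of the cell leading edge, 53 fell and 16 rose (adjusted p = 0.000194; adjusted p = 0.901 with an estimated correlation), and of 69 genes of the actin cytoskeleton 45 fell and 13 rose (adjusted p = 0.00488; adjusted p = 0.901 with an estimated correlation). Terms for actin binding (27 of 50 lower and 7 higher; adjusted p = 0.0205; adjusted p = 0.878 with an estimated correlation) and actin filament polymerization (20 of 28 lower and 4 higher; adjusted p = 0.0179; adjusted p = 0.806 with an estimated correlation) were also called lower, whereas those for actin filaments (adjusted p = 0.406), actin filament bundles (adjusted p = 0.277) and ruffles (adjusted p = 0.346) were not called. Genes for Ras guanyl-nucleotide exchange fell in 32 of 57 cases and rose in 8 (adjusted p = 0.000239; adjusted p = 0.878 with an estimated correlation). Of 47 phagocytosis genes, 29 fell and 10 rose (camera adjusted p = 0.00051, and adjusted p = 0.806 with an estimated correlation). Across all tested genes 31.8% fell, whereas among genes spanning at least 66.7 kb 63.1% fell and 12.2% rose, a trend described below. The genomic spans of genes in the terms called lower, here and below, were not examined. A share of that trend in their falls was therefore not tested.

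Of 46 genes of microbodies, the class of organelle that includes peroxisomes, 28 rose and 8 fell (camera adjusted p = 0.00933; adjusted p = 0.901 with an estimated correlation), whereas the related term for parts of the peroxisome, with 17 of 39 higher and 9 lower, was not called (adjusted p = 0.18). Of 28 genes of the protein serine/threonine phosphatase complex 22 fell and none of the others rose by the test (adjusted p = 0.0123; adjusted p = 0.901 with an estimated correlation), and of 15 genes for binding to CCR chemokine receptors 12 fell (adjusted p = 3.15e-09; adjusted p = 0.878 with an estimated correlation). In all, 7 of 752 terms for biological processes were called higher and 42 lower, 4 of 198 terms for molecular functions higher and 14 lower, and 1 of 160 terms for cellular components higher and 11 lower. The nuclear RNAs Malat1 and Neat1, chosen after their values were seen, rose from 412.5 ± 52.5 to 835.3 ± 148 CPM and from 816.3 ± 50.1 to 1555 ± 26.1 CPM (SD, n = 3).

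Genes with long genomic spans fell with DA more often than short ones. Among the 2388 genes spanning at least 66.7 kb 63.1% fell and 12.2% rose, with a median log2 fold change of -0.50, against 16% and 48% and a median of 0.23 among the 2388 genes of up to 8.5 kb. The tables argue against mature transcript length, GC content and low counts as the whole cause: the weakest correlation of the change with span was -0.134 within 5 equal classes of mature length, -0.24 within 5 of GC content and -0.357 in the 2 highest of 5 classes of expression, where a simulated change that followed mature length alone gave 0.008 as its weakest value. A lower share of nuclear RNA in the DA libraries cannot be told apart from an effect of DA on the genes, because Malat1 and Neat1 rose (mean log2 fold change 0.97) while the nuclear Kcnq1ot1, also chosen after its value was seen, fell (-0.30). That DA lowered the output of long genes may explain the pattern and stays an untested hypothesis, since steady-state counts hold no measure of elongation or of RNA stability.

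Sterol synthesis genes rose together while Abca1 and Abcg1, cholesterol exporter genes chosen after their values were seen, fell from 740.9 ± 97.4 to 184.5 ± 22.9 CPM and from 93.4 ± 2.84 to 33.5 ± 2.53 CPM (SD, n = 3). Trends with GC content, mature length and span do not account for it, since their removal left the median of the synthesis list at 1.92 (2.09 before) and the mean of both exporter genes at -1.37. A few genes taking most of the counts would move all other genes by 1 factor, but the median of the list lay 2.07 above that of all tested genes, more than the list's SD of 0.73, while both exporter genes fell. Lower LXR activity cannot be told apart from other changes, because 7 LXR targets went both ways, 4 rising and 3 falling, with a median of 0.16 and an SD of 1.12. Abca1 and Abcg1 were themselves among the 7, so their falls are no separate evidence. Of the others, Mylip (log2 fold change 0.511), Srebf1 (0.599), Lpcat3 (0.155) and Apoe (0.205) rose and Nr1h3 (-1.586) fell. A lower sterol level sensed by the cells with DA may raise synthesis genes and lower exporters, a hypothesis for which sterols were not measured in the data used here.

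S100a8 rose 6.40-fold with DA, from 63.5 ± 12.6 to 406.3 ± 14.6 CPM (SD, n = 3), and among the other neutrophil markers Mmp8 (log2 fold change 1.73) and Cxcr2 (0.48) rose as well. These genes were singled out after their values were seen. More neutrophils in the DA cultures would raise their abundant transcripts together, but the median of the 8 other markers expressed enough to test was -0.15 (SD 0.71), and S100a9 stood at 93.2 ± 9.17 and 99.8 ± 2.9 CPM (SD, n = 3). The tables therefore argue against neutrophils as the source of the rise. A change of S100a8 within the macrophages may account for it and was not tested.

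The 6 libraries can be divided into 3 and 3 in 10 ways, which is too few for a share under 0.05. The number of splits with a result as large, the real one included, was 1 for genes changed (7981 in the real split, at most 0 in another), 1 for genes higher (4043 and 0), 1 for genes lower (3938 and 0) and 1 for genes changed at least 2-fold (1837 and 0). In those other splits edgeR gave 40 to 135 genes an unadjusted p under 0.05, against 8352 in the real one. For pathway lists called by camera with the preset correlation the number was 3 (10 lists in the real split, at most 11 in another), and for Gene Ontology terms it was 1 (79 and 20). Every other split mixes both groups and so carries the DA difference in its spread and part of it in its contrast, and these numbers are not rates of false calls.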
